A study of Mus musculus with 6 samples.

How the data were processed

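Cerebellum RNA of 6 mice (C57BL/6J, postnatal day 60) was profiled by RNA sequencing, with 3 animals labelled WT and 3 labelled Slc7a5-KO. Per the labels, all 6 carried Tie2-Cre, a recombinase active in endothelial and blood lineages. The WT animals had 1 floxed Slc7a5 allele and the Slc7a5-KO animals had both alleles floxed. Per the labels' protocols, libraries came from total RNA with a SENSE mRNA-Seq V2 kit, which keeps the strand. Each library came from its own animal, so the replicates are separate mice. Sex was not given in the labels and was read here from Xist and Y-linked genes.

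The deposited values are read counts per gene, not normalised, with 1 table per animal. Per the submitters' processing notes, STAR 2.5.4 was used with the genome build GRCm38 (mm10). The annotation release and any removal of PCR duplicates are not given in the sources used here, and no molecular identifiers are described, so counts may include PCR copies. Each table lists 3 counts per gene, for both strands together and for each strand apart. The reverse-strand count held 94.8% to 95.8% of the reads of both strand columns and was used, by a rule that required over 90%. Multimapping reads are listed as 0 in every table, so genes with near-identical copies, such as ribosomal protein genes, globins and metallothioneins, have uncertain levels. Reads assigned to no gene or to several genes were 19.5% to 22.2% of the aligned reads and stayed out of library sizes and tests.

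A further deposited table holds the authors' own comparison of the same libraries. Per the submitters' processing notes, DESeq2 1.10.1 in R 3.2.4 was used. Per the file headers, the table gives a mean normalised count (the signal over all 6 libraries), log2 fold changes with and without shrinkage, a Wald score, and a p-value with its adjusted value. The authors' design formula and filters are not given in the sources used here. The table's mean values were checked against the counts: of 13012 genes with a mean over 50, 99.9% matched the reverse-strand counts within 0.1%.

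Gene symbols were matched for 46488 of 46983 gene identifiers, and coordinates come from GENCODE release M21 on GRCm38. Depth was 13.4 to 34.2 M gene reads (M, mega) per library. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 16851. Libraries were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, robust, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a false discovery rate of 0.05. CPM, counts per M reads, are TMM-scaled, and log2 CPM used a prior count of 2. Values after ± are SD for CPM and standard errors for log2 fold changes, with n = 3 animals per group. With the biological coefficient of variation at 31.6%, power was limited. On simulated data with 200 changed genes among 16851, edgeR called 17.9% of genes changed by 1.5-fold, 70.1% by 2-fold and 93.9% by 4-fold, with 13 calls among unchanged genes. The changed genes were drawn only from those above a floor of mean CPM, and 1 gene list was shifted by a log2 of 0.5 as well. Counts were drawn independently for each gene, with no animal set apart. These shares may thus overstate the power here, above all for low genes.

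The groups, the tests, the 33 gene lists and most alternatives were chosen before the data were examined. The lists cover amino acid sensing and metabolism, translation, stress, receptors, and markers of cell types that cerebellum tissue or its dissection can hold. The sex-linked list was not tested, which left 32. Lists were tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01), adjusted over the 32 lists, and again with an estimated correlation and with fry. A list score is the mean over members of log2 CPM centred on each gene's mean over the 6 animals. Slc7a5 relative to endothelial markers was tested with a 2-sided exact permutation test, whose smallest possible p is 0.1 for 3 against 3.

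The named genes follow a rule set at the same time. It takes Slc7a5 and Slc3a2, then up to 12 genes each way by fold change among those past the threshold, with a mean CPM of at least 1 and no overlap between groups. From each list it takes up to 5 genes past the threshold, or the 2 with the smallest p. With fewer than 10 genes past the threshold, it adds the 10 with the smallest p each way. Genes outside the rule are said to have been chosen after their values were seen. Alternatives were other scalings, filters, count columns and tests (DESeq2 1.42.0, limma-voom), a replicate block, and leaving out each library. Added after seeing the data were a sex term, offsets for GC content and length, thinning to the shallowest library, and DESeq2 with its older prior. All 6 libraries were kept.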

Results

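Cerebellum transcriptomes were compared between 3 mice labelled WT and 3 labelled Slc7a5-KO. Slc7a5 encodes LAT1, a transporter of large neutral amino acids such as leucine, and the series asks what its loss from brain vessels does to the brain. Gene reads were 34.2, 29.6 and 27.7 M in WT replicates 1 to 3. They were 31.1, 27.3 and 13.4 M in the Slc7a5-KO libraries, so replicate 3 was the shallowest. Slc7a5-KO replicate 2 had more genes at very low counts, with 699 genes at 2 reads against 230 to 308 in the other libraries. It also had the most genes detected (21172), and the cause was not tested. By Xist and Y-linked genes, the WT group held 1 female and 2 males and the Slc7a5-KO group 2 females and 1 male. Principal component 1 (34% of variance) set Slc7a5-KO replicate 3 apart from the other libraries, and component 2 (24.7%) set WT replicate 2 apart.

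Slc7a5 transcript was not lower in the libraries labelled Slc7a5-KO. Slc7a5 (ENSMUSG00000040010.10, GRCm38 chromosome 8, 121881150 to 121907694, minus strand, protein-coding) stood at 72.0, 66.3 and 43.2 CPM in WT replicates 1 to 3. It stood at 164, 59.4 and 118 CPM in the libraries labelled Slc7a5-KO. The log2 fold change was 0.91 ± 0.42 (edgeR adjusted p = 0.84). Without Slc7a5-KO replicate 2 it was 1.22 (edgeR adjusted p = 0.010), higher in the libraries labelled Slc7a5-KO, and without Slc7a5-KO replicate 1 it was 0.55 (edgeR adjusted p = 0.75). Slc3a2, which encodes the heavy chain that LAT1 pairs with, had a log2 fold change of 0.27 ± 0.14 (edgeR adjusted p = 0.83). Its value ran from 0.16 to 0.39 when 1 library was left out. Relative to the mean of 30 endothelial and blood-brain barrier markers, Slc7a5 differed by 0.77 ± 0.52 (log2, 2-sided exact permutation p = 0.3, smallest possible 0.1). The deleted part of the gene is not given in the sources used here, and whole cerebellum holds many cells outside the Tie2 lineage, so a count over the whole gene is a weak check of the labels. All directions given for other genes follow the labels, which the Slc7a5 counts did not bear out.

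8 genes rose in the libraries labelled Slc7a5-KO, and none fell at a false discovery rate of 0.05. Atf5, a transcription factor of the amino acid and stress response, went from 23.1 ± 3.13 to 74.9 ± 14.8 CPM (log2 1.70 ± 0.17, edgeR adjusted p = 0.00017). Chac1, an enzyme that degrades glutathione, went from 14.7 ± 2.03 to 38.1 ± 6.70 CPM (log2 1.38 ± 0.20). Slc7a1, a transporter of cationic amino acids, rose from 46.6 ± 8.12 to 97.6 ± 8.47 CPM (log2 1.07 ± 0.15). Slc1a4, a transporter of neutral amino acids including serine, rose from 53.2 ± 3.33 to 108 ± 1.92 CPM (log2 1.02 ± 0.13). Shmt2, the mitochondrial serine hydroxymethyltransferase, rose from 38.2 ± 1.097 to 74.1 ± 7.56 CPM (log2 0.96 ± 0.14). On GRCm38, Atf5 lies on chromosome 7 (44812256 to 44816658, minus strand), Chac1 on 2 (119351229 to 119354381, plus), Slc7a1 on 5 (148327410 to 148399904, minus), Slc1a4 on 11 (20302180 to 20332713, minus) and Shmt2 on 10 (127517123 to 127522444, minus). The edgeR adjusted p was 0.0029 for Slc1a4, 0.0055 for Chac1 and Slc7a1, and 0.0098 for Shmt2.

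Trim66, Caly and Ostn passed by less, each with an edgeR adjusted p of 0.044. Trim66 rose by 0.89 ± 0.16 and Caly, a neuronal vesicle protein, by 0.80 ± 0.14 on the log2 scale. Ostn, which encodes the secreted peptide osteocrin, was low throughout, at 0.198, 0.397 and 0.905 CPM in WT and 10.96, 2.02 and 9.63 CPM in the libraries labelled Slc7a5-KO (log2 3.92 ± 0.66). Ostn lies on chromosome 16 (27307489 to 27351212, plus strand), and Trim66 and Caly on 7 (109449006 to 109508134 and 140069880 to 140082548, both minus). Leaving out WT replicate 3 ended the call of Chac1 (edgeR adjusted p = 0.068) and Shmt2 (0.14), and leaving out WT replicate 1 that of Shmt2 (0.068). Trim66 and Caly lost theirs without any 1 of the WT replicates or without Slc7a5-KO replicate 3, with edgeR adjusted p up to 0.25 and 0.37. Ostn lost its call without any 1 library except Slc7a5-KO replicate 2, with edgeR adjusted p up to 0.38. All 8 genes separated the groups without overlap. They were therefore bound to be higher in both sexes, which adds no support, and the WT group held 1 female and the Slc7a5-KO group 1 male. Of the 16851 genes tested, 11.5% separated the groups, against 10% by chance. At an unadjusted p under 0.05 edgeR gave 1048 genes, 582 higher and 466 lower, against 843 by chance. DESeq2 called 45 genes, 39 higher and 6 lower. On the simulated data DESeq2 made 33 calls among unchanged genes and edgeR 13, so part of the larger count may be false calls. The edgeR count fell to 3 without WT replicate 3 and to 5 without WT replicate 1 or Slc7a5-KO replicate 3. It was 20 without Slc7a5-KO replicate 1 and 20 without Slc7a5-KO replicate 2.

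**Figure D1:**
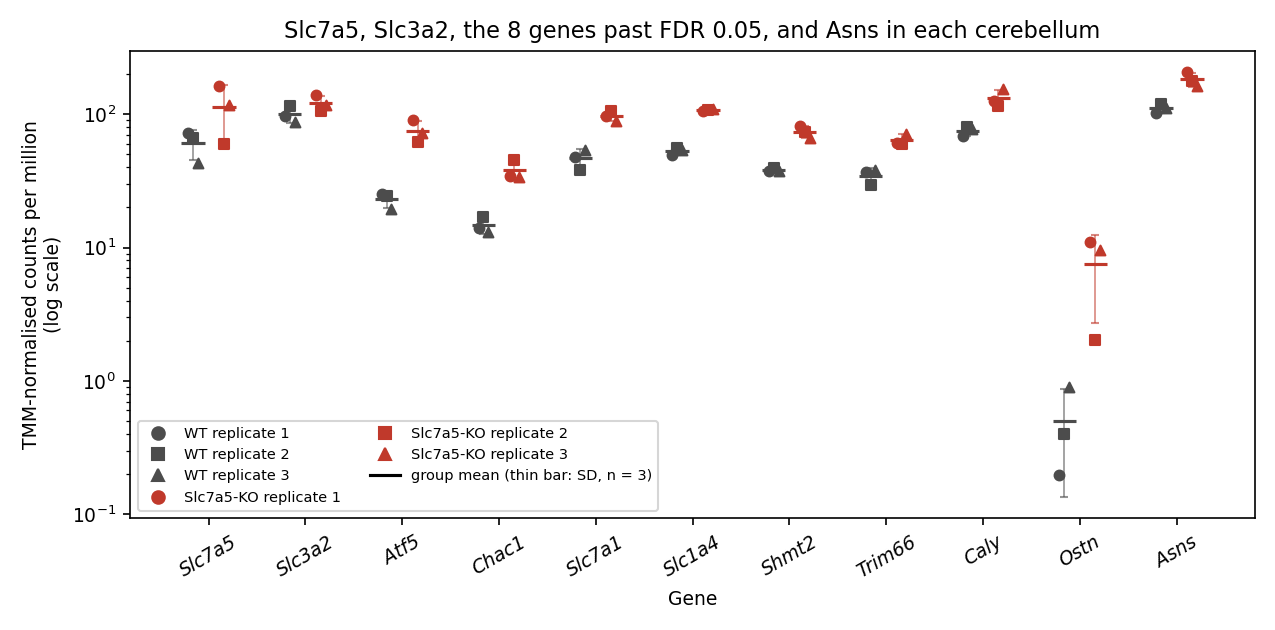
TMM-scaled CPM on a log scale for Slc7a5, Slc3a2, the 8 genes past the threshold and Asns, with 1 point per animal (n = 3 per group), thick bars for group means and thin bars for SD. Slc7a5 spans 43.2 to 72.0 in WT and 59.4 to 164 in the libraries labelled Slc7a5-KO, while Atf5 spans 19.5 to 25.2 and 61.9 to 91.1.

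The list of ATF4 amino acid response targets, genes induced when amino acids are short, was higher in the libraries labelled Slc7a5-KO. Its median log2 fold change was 0.61, and 35 of 36 members were above 0 (camera adjusted p = 2.8e-32, adjusted p = 0.092 with an estimated correlation). Atf5, Chac1, Slc7a1 and Shmt2 rose over all genes tested, and 18 members, all higher, passed when adjusted over the list alone. Asns, asparagine synthetase, stood at 112 ± 8.76 and 183 ± 23.0 CPM (log2 0.71 ± 0.13) and missed the threshold over all genes, with an edgeR adjusted p of 0.064. Atf4 itself, chosen after its values were seen, had a log2 value of 0.42 ± 0.13 (edgeR adjusted p = 0.53), and Trib3 and Ddit3, chosen likewise, had 1.53 ± 0.50 and 0.57 ± 0.19 (edgeR adjusted p = 0.59). The lowest list score among the libraries labelled Slc7a5-KO lay 0.39 above the highest WT score. The list median was 0.56 in females and 0.61 in males. Since the scores did not overlap, a rise of the list mean in both sexes was fixed in advance, so this adds no support.

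The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were also higher as a list. The median log2 fold change was 0.30, and 17 of 20 members were above 0 (camera adjusted p = 1.5e-09, adjusted p = 0.26 with an estimated correlation). No member passed over all genes by edgeR, and 8 did when adjusted over the list alone. These were Cars (log2 0.90 ± 0.17) and Gars (0.57 ± 0.12), and, chosen after their values were seen, Mars, Yars, Aars, Iars, Sars and Nars. Lars, the leucine synthetase, chosen likewise, had 0.33 ± 0.18 (edgeR adjusted p = 0.85). The list median was 0.30 in females and 0.30 in males. The list scores of the groups did not overlap here either, so a rise in both sexes adds no support. The mitochondrial synthetases were not called, with a median of 0.13 (camera adjusted p = 0.76), and 0.05 to 0.125 when 1 library was left out.

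Amino acid transporters and serine, glycine and one-carbon synthesis were called higher as well. The 30 transporters had a median of 0.11 (camera adjusted p = 0.00017, adjusted p = 0.26 with an estimated correlation). Slc1a4 and Slc7a1 rose over all genes and 3 members passed when adjusted over the list alone, the other being Slc7a3, chosen after its values were seen (log2 1.05 ± 0.22, edgeR adjusted p = 0.16). The 16 genes of serine, glycine and one-carbon synthesis had a median of 0.16 (camera adjusted p = 5.0e-06, adjusted p = 0.26 with an estimated correlation). Shmt2 rose over all genes, and 5 members passed when adjusted over the list alone. The transporter median was 0.26 in females and 0.03 in males, and the serine list median 0.28 and 0.18. Scores of both lists separated the groups, so a rise in both sexes adds no support. The transporter median was 0.20 without WT replicate 1 or Slc7a5-KO replicate 2, 0.07 without WT replicate 2 and 0.05 without Slc7a5-KO replicate 3. The serine list median was 0.33 without WT replicate 1, 0.34 without Slc7a5-KO replicate 3 and 0.13 without WT replicate 3. These lists overlap the ATF4 list, and a test of the members not shared was chosen after the values were seen. Without the 7 shared genes, the 9 left in the serine list had a median of 0.03 (camera unadjusted p = 0.83), and without 4 shared genes the 26 transporters left had 0.09 (camera unadjusted p = 0.012, or 0.19 with an estimated correlation).

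Markers of Purkinje cells, the output neurons of the cerebellar cortex, were lower in the libraries labelled Slc7a5-KO. The median log2 fold change was -0.37, and 18 of 20 members were below 0 (camera adjusted p = 2.2e-12, adjusted p = 0.39 with an estimated correlation). No member passed over all genes by edgeR, and 5 lower members passed when adjusted over the list alone. Rgs8, a regulator of G-protein signalling, stood at 912 ± 91.5 and 615 ± 44.8 CPM (log2 -0.57 ± 0.13, edgeR adjusted p = 0.22). Icmt, an enzyme of protein methylation, had -0.48 ± 0.12 (edgeR adjusted p = 0.29). The others were Pvalb (-0.48 ± 0.14), Homer3 (-0.47 ± 0.14) and Calb1 (-0.55 ± 0.19), chosen after their values were seen. Pcp2, also chosen then, had -0.21 ± 0.16, and from -0.33 to 0.008 when 1 library was left out. The list median was -0.53 in females and -0.46 in males. The lowest WT score lay 0.077 above the highest score of the libraries labelled Slc7a5-KO, so a fall in both sexes adds no support. The highest list score, 0.41, was in WT replicate 2, the animal apart on component 2, and without it the median was -0.23. The camera adjusted p was then 2.9e-06 with the preset correlation of 0.01. The correlation estimated for this list with all 6 libraries was 0.46, so that p does not show that the fall holds without this animal.

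Other cell type lists moved less or rested on 1 animal. Choroid plexus markers had a median of -0.70 (camera adjusted p = 0.00087, adjusted p = 0.96 with an estimated correlation), with 15 of 16 members below 0. Slc5a5 went the other way, at 0.89 ± 0.28 (edgeR adjusted p = 0.55). Ttr, an abundant choroid plexus transcript chosen after its values were seen, stood at 15.5 CPM in Slc7a5-KO replicate 2 and at 2158 to 5317 CPM in the other 5 libraries. The list median was -0.47 in females and -3.50 in males, where that replicate is the only Slc7a5-KO animal. Without it the choroid plexus median was -0.20 (camera adjusted p = 0.13), and without Slc7a5-KO replicate 3 it was -1.35. Microglia and macrophage markers had a median of 0.16 (camera adjusted p = 0.0092, adjusted p = 0.50 with an estimated correlation). Cd68, a lysosomal protein of phagocytes, had 1.26 ± 0.29 (edgeR adjusted p = 0.21) and Cx3cr1, the fractalkine receptor, 0.52 ± 0.17 (edgeR adjusted p = 0.59). P2ry12, chosen after its values were seen, had -0.02 ± 0.18. The microglia call ended without WT replicate 3 (median 0.07, camera adjusted p = 0.25) and with a sex term (camera adjusted p = 0.054). Its median was 0.31 without WT replicate 2, and -0.14 in females and 0.44 in males.

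Immediate early genes, induced by neuronal activity, had a median of 0.36, with 18 of 20 members above 0 (camera adjusted p = 0.00016, adjusted p = 0.47 with an estimated correlation). Egr1 stood at 26.9 ± 1.50 and 55.2 ± 17.1 CPM (log2 1.04 ± 0.20, edgeR adjusted p = 0.068), and 1 member passed when adjusted over the list alone. The list median was 0.78 in females and 0.12 in males. The score of WT replicate 1 (0.17) lay above that of Slc7a5-KO replicate 2 (0.02). The median was 0.66 without WT replicate 1, 0.22 without WT replicate 3 and 0.23 without Slc7a5-KO replicate 1.

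**Figure D2:**
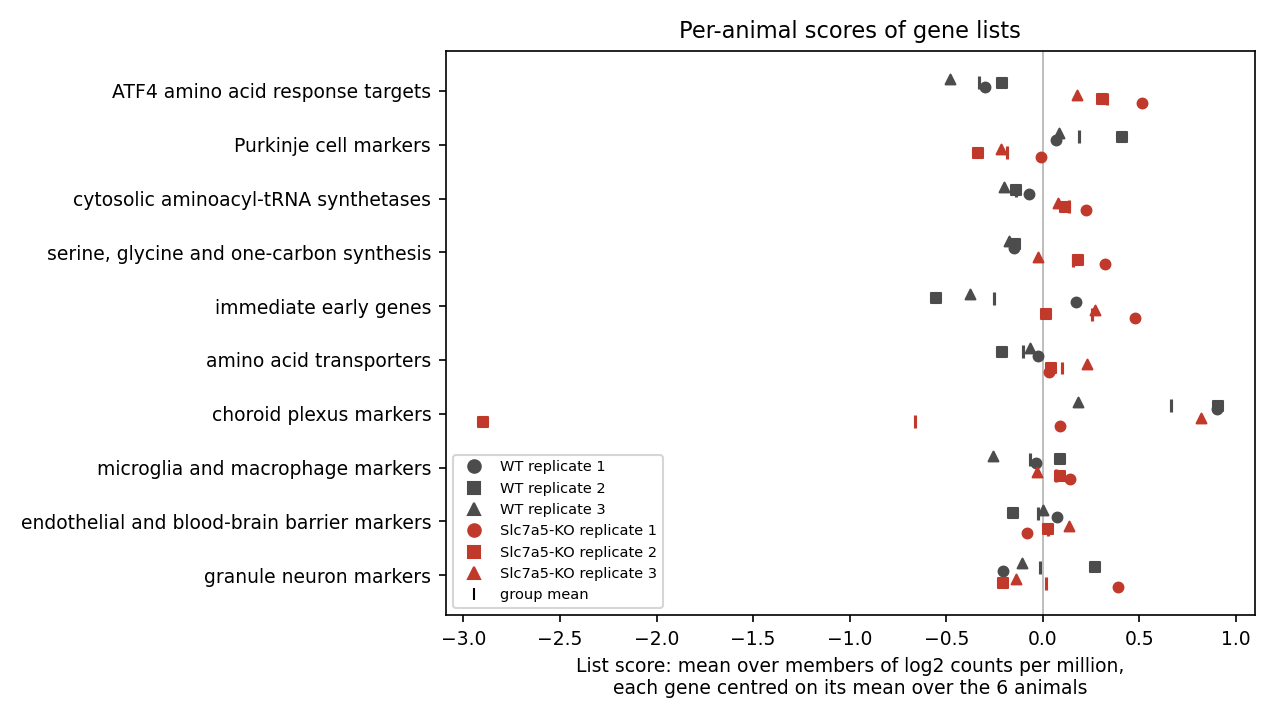
Scores of 10 gene lists in each animal: the mean over members of log2 CPM, each gene centred on its mean over the 6 animals, with 1 point per animal and a tick for each group mean (n = 3 per group). The ATF4 scores of the libraries labelled Slc7a5-KO run from 0.18 to 0.51, all above WT, and Slc7a5-KO replicate 2 lies at -2.90 for choroid plexus markers.

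No gene was called lower by edgeR, where 466 were lower at an unadjusted p under 0.05, DESeq2 called 6 and limma-voom none. The 10 lower genes with the smallest p had edgeR adjusted p of 0.17 to 0.29 and did not pass. They were Eef1akmt1 (log2 -1.02 ± 0.22), Dynlrb2 (-2.40 ± 0.53), Ndufb4, a subunit of respiratory complex I (-0.63 ± 0.15), Rgs8, Slc31a1, a copper transporter (-0.74 ± 0.18), Icmt, Gkn3 (-1.34 ± 0.34), Calml4, Wdfy1 and Polr3k. Dynlrb2 was low, at 4.59 ± 0.96 and 0.89 ± 0.45 CPM. Among higher genes, Cyb5r1 also missed the threshold (log2 0.96 ± 0.18, edgeR adjusted p = 0.064).

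The other 24 lists were not called, with camera adjusted p of 0.13 to 0.95. Endothelial and blood-brain barrier markers had a median of 0.08, with 17 members above 0 and 13 below. The 2 with the smallest p were both lower and did not pass. Itm2a had -0.43 ± 0.14 (edgeR adjusted p = 0.59) and Tfrc -0.34 ± 0.13 (edgeR adjusted p = 0.74). Slc2a1, the glucose transporter of that barrier, had -0.02 ± 0.14 and Cldn5 0.37 ± 0.29, both chosen after their values were seen. Branched-chain amino acid catabolism had -0.05, mTORC1 amino acid sensing -0.02, translation initiation factors 0.04, cytosolic ribosomal proteins -0.08 and ER chaperones 0.06. Astrocyte and Bergmann glia markers had -0.11 (-0.14 to -0.08 when 1 library was left out) and glutamate receptor subunits 0.04 (0.01 to 0.11). Leaving out 1 library moved these medians, from -0.15 to -0.05 for branched-chain catabolism, -0.06 to 0.0039 for mTORC1 sensing, 0.01 to 0.08 for initiation factors, -0.18 to 0.08 for ribosomal proteins, -0.02 to 0.08 for ER chaperones and 0.04 to 0.19 for endothelial markers. Ribosomal proteins were called lower without WT replicate 1 (-0.18, camera adjusted p = 0.0061) but had 0.08 without WT replicate 2. Branched-chain catabolism was called lower without WT replicate 3 (-0.09, camera adjusted p = 0.023), by DESeq2 with and without its older prior, and with a sex term. Astrocyte markers were called lower without Slc7a5-KO replicate 3 (-0.13, camera adjusted p = 0.043), by limma-voom, by DESeq2 with and without its older prior, and with a sex term. In the main comparison 14 astrocyte markers were below 0 and 6 above, and the 1 that passed over the list alone was higher. Of the 2 with the smallest p, Gfap was higher (0.55 ± 0.14, edgeR adjusted p = 0.31). S100b was lower (-0.38 ± 0.13, edgeR adjusted p = 0.64). In 7 lists, none of them called, the median, the mean and the test differed in sign, among them granule neuron markers (median -0.13, mean 0.03). Within that list Calb2, the calcium-binding protein calretinin, stood at 264 ± 27.4 and 606 ± 217 CPM (log2 1.20 ± 0.21, edgeR adjusted p = 0.068).

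The authors' deposited table made the same comparison. It listed 131 genes at an adjusted p under 0.05, 91 higher and 40 lower in the libraries labelled Slc7a5-KO. Across 16642 genes, which are not independent replicates, its unshrunken log2 fold changes and those of edgeR had a Pearson correlation of 0.998 and a Spearman correlation of 1.00. All 131 had the same sign in edgeR and an unadjusted edgeR p under 0.05, and all 8 genes called by edgeR were among them. In the authors' deposited table Slc7a5 had an unshrunken log2 fold change of 0.91 and an adjusted p of 0.45.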

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

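The test of an interaction between sex and group was chosen after the data were seen. It compared the difference between the libraries labelled Slc7a5-KO and WT in females with that in males, with sex read from the data. By edgeR, 39 genes passed an adjusted p of 0.05, and 1304 passed at an unadjusted p of 0.05. The female WT and the male Slc7a5-KO group are 1 animal each, so a difference between sexes cannot be separated from those animals. Of the 39 genes, 12 had their lowest CPM in Slc7a5-KO replicate 2, the library low in choroid plexus transcripts, and 5 were in the choroid plexus list. In 23, 5 of them among those 12, the highest CPM was in WT replicate 2, so 30 of the 39 had either. The rest, such as Ddn and Fos, had their highest CPM in Slc7a5-KO replicate 2 or their lowest in WT replicate 2. All 39 thus had an extreme value in at least 1 of these 2 animals. Slc7a5 did not pass, with log2 fold changes of 1.07 in females and 0.09 in males (edgeR interaction adjusted p = 0.47).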

How the results depend on the processing

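The sex term, the GC and length offsets, thinning and DESeq2 with its older prior were chosen after seeing the data. The 8 called genes kept their direction under all 20 alternatives each, and 126 of 160 values stayed past the threshold. Atf5, Slc7a1 and Slc1a4 stayed past it in each of those 20, which leave out the 1.5-fold test, and Caly, Ostn and Trim66 lost it in 11, 10 and 10. The count of 8 genes (8 higher, 0 lower) was 71 without a low-count filter (55 higher, 16 lower), 45 by DESeq2 (39 and 6), 43 by DESeq2 with its older prior (37 and 6), 16 with a sex term (5 lower), and 14 at a false discovery rate of 0.10 (14 higher). It was 5 with CPM of at least 1 in 3 samples (5 higher), 5 without robust shrinkage (5 higher), and 1 when tested against 1.5-fold (1 higher). Leaving out 1 library gave 3 to 20 genes, 3 to 20 higher and 0 to 3 lower. Slc7a5 ranged from 0.55 to 1.22 when 1 library was left out and passed only without Slc7a5-KO replicate 2 (1.22). The cause of these changes was not tested.

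The 8 called lists became 13 with a sex term, 0 with an estimated correlation, 0 by directional fry (4 by mixed fry, which ignores direction), and 8 to 12 when 1 library was left out. Granule neuron markers, at a median of -0.13 with a test direction of higher, were called lower without Slc7a5-KO replicate 1 (-0.37) and with a sex term (-0.25). Myelin markers, not called, were called higher in the same settings (0.20 and 0.17). When 1 library was left out their medians ran from -0.37 to 0.034 and from -0.15 to 0.20. Other lists not called in the main comparison gained a call: meningeal fibroblast markers without WT replicate 3 (-0.19), Slc7a5-KO replicate 1 (-0.06) or 3 (-0.30) and with a sex term (-0.27), neighbouring brain regions without Slc7a5-KO replicate 1 (0.28) and with a sex term (0.39), myelin markers, lower, without Slc7a5-KO replicate 2 (-0.15), blood cell genes without WT replicate 2 (0.80), and mitochondrially encoded mRNAs with GC and length offsets (0.27). The correlation with the deposited table was 0.669 for unstranded counts and 0.997 for DESeq2. A replicate block gave 6 genes (6 higher, 0 lower) and 8 lists. Same-numbered libraries correlated at -0.038, -0.059 and -0.027 after removing group means, so the numbers were not taken as pairing. With 3 animals per group, simulated 1.5-fold changes were called in 17.9% of genes, all above a floor of mean CPM. Thinning to the shallowest library gave 6 genes, all among the 8.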

Other observations

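Some transcripts called by DESeq2 or by the authors' deposited table missed the edgeR threshold, and are named here after their values were seen. Vgf, a neuropeptide precursor, stood at 20.9 ± 3.05 CPM in WT and 52.7 ± 23.8 CPM in the libraries labelled Slc7a5-KO (log2 1.33 ± 0.26, edgeR adjusted p = 0.16). Sst, which encodes somatostatin, had a log2 value of 0.83 ± 0.18 (edgeR adjusted p = 0.18) and Nrgn, neurogranin, 0.74 ± 0.17 (edgeR adjusted p = 0.19). Gpnmb, a glycoprotein of phagocytes and other cells, had 2.10 ± 0.42 from a low level of 1.60 ± 0.31 CPM (edgeR adjusted p = 0.092).

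Tissue content differed between animals. Slc6a3, the dopamine transporter, stood at 61.5 CPM in Slc7a5-KO replicate 3 and at 0.036 to 3.74 CPM in the other 5 libraries. Th, tyrosine hydroxylase, stood at 93.2 CPM in that library and at 19.3 to 31.8 CPM in the others. The list of brain regions next to the cerebellum, to which both genes belong, did not stand out in that library. Its scores were 0.63, -1.06 and 0.51 in WT replicates 1 to 3, and -0.85, 0.75 and 0.02 in Slc7a5-KO replicates 1 to 3. Slc7a5-KO replicate 2, with the highest of these, also had the highest myelin (0.34) and oligodendrocyte precursor (0.20) scores and the lowest Purkinje score (-0.34). WT replicate 2, with the lowest, had the highest Purkinje score (0.41).

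Apart from other splits of the animals, the tests that follow were chosen after the results that prompted them were seen. They concern sex, GC content and length, labels, endothelial RNA, dilution and respiratory genes. The fits without 1 library were planned, but their use as tests was chosen likewise. The criteria for labels, endothelial RNA and dilution were also changed after their own values were seen. Among the 10 splits of the 6 animals into 3 and 3, the real split called 8 genes, and it alone (1 of 10) reached that number. The highest of the others, 7, was the split that parts females from males. With 10 splits the share cannot go under 0.1. For lists the real split called 8 and the highest other 13, and 7 of 10 splits, the real one included, called at least 8, so the number of lists called with a preset correlation did not set the real groups apart. The ATF4 list had an absolute median of 0.61 in the real split and at most 0.33 in the others, although 5 of the other 9 splits also called it.

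The rise of the ATF4 list was weighed against 4 technical explanations. Unequal sexes would bring its mean shift near 0 in a model with sex, where it was 0.63 ± 0.14. GC content or length bias would bring its median under 0.3, and with offsets for both it was 0.59. Tissue from beside the cerebellum or low depth in Slc7a5-KO replicate 3, or missing choroid plexus in Slc7a5-KO replicate 2, would do so when that library was left out, and the medians were then 0.66 and 0.56. These values argue against each of these as the whole cause, and chance stays open with 10 splits. A response to the genotype remains a hypothesis. The Slc7a5 counts did not bear out the labels, but as a weak check they do not speak against such a response either.

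Why Slc7a5 was not lower in the libraries labelled Slc7a5-KO stays open. A wrong label of 1 Slc7a5-KO library cannot be told apart: the lowest ATF4 score lay 0.39 above the highest WT score, with an SD of at most 0.17 within groups, but this bears on labels only if the ATF4 list follows genotype, which is itself open. Labels exchanged between whole groups were not tested. More endothelial RNA would raise the 30 endothelial markers by about the 0.91 ± 0.42 of Slc7a5. Their median was 0.080, with an SD of 0.32 over markers and not over animals, and the highest was 0.63. The markers as a set thus did not rise by as much. This form of the comparison was set after its values were seen. The first form, Slc7a5 less the endothelial mean, gave 0.77 ± 0.52 and did not decide, so endothelial RNA is not excluded. Unequal sexes cannot be told apart as a cause of the Slc7a5 difference, with 0.58 ± 0.42 in a model with sex. Transcript from outside the deleted part of the gene or from other cells was not tested.

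For the fall of the Purkinje list, chance, dilution by neighbouring tissue and an uneven sampling of cerebellar regions stay open, and the last was not tested. Dilution by neighbouring tissue would lower granule neuron markers alike, and the Purkinje median lay -0.23 ± 0.11 from theirs, from -0.37 without Slc7a5-KO replicate 3 to -0.10 ± 0.13 without Slc7a5-KO replicate 1. In a model with sex the mean shift was -0.47 ± 0.079, and with offsets for GC content and length the median was -0.39, which argues against each of these as the whole cause. Dilution would also raise markers of neighbouring regions, whose median was 0.02 with all 6 libraries. Their median was -0.28 without WT replicate 2 and -0.37 without Slc7a5-KO replicate 2, where the Purkinje median was -0.23 and -0.30. Without WT replicate 1 it was 0.29 and without Slc7a5-KO replicate 1 0.28, where the Purkinje median was -0.45 and -0.47. Without WT replicate 3 or Slc7a5-KO replicate 3 the neighbouring median was 0.09. These values did not decide on dilution. Markers of neighbouring regions went both ways, and the gap between Purkinje and granule medians was within its error of 0 without Slc7a5-KO replicate 1. The bound set for that gap, under -0.2 by more than its error in each setting, was missed already with all 6 libraries. WT replicate 2 had the lowest score for neighbouring regions and the highest Purkinje score. Slc7a5-KO replicate 2 had the reverse, and both go with dilution.

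After Ndufb4 and other respiratory chain genes were noticed among the lower genes of the authors' deposited table, a lower level of the whole set of nuclear genes for respiratory complex subunits was tested as a hypothesis. The 83 genes had a median log2 fold change of -0.18, with 67 below 0 (camera unadjusted p = 1.1e-07, p = 0.22 with an estimated correlation). The set scores of the groups overlapped, so the test did not decide.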
